A study of Zea mays with 6 samples.

How the data were processed

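RNA from mature pollen of the maize inbred line B73 was sequenced after 2 treatments. Plants of the control group stayed at 25 °C by day and 21 °C by night. Plants of the heat group, chosen when their developing pollen was at the tetrad stage (the 4 joined microspores that follow meiosis), spent 48 h in a chamber at 35 °C by day and 25 °C by night, with both groups at 60% humidity. All plants then went back to the greenhouse until the pollen was mature, so the libraries describe pollen collected well after the heat had ended. Each group had 3 libraries, which the labels call biological replicates, made with a strand-marking mRNA kit per the labels' protocols.

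The deposited table gives TPM (a gene's reads divided by its length, scaled so that each library sums to the same total), and was used as the authors made it. Per the submitters' processing notes, Trimmomatic 0.35, FastQC, STAR 2.5.2a, featureCounts and DESeq2 were used and the genome build was B73 RefGen_v3. The role of each tool is not given in the sources used here. Nor are the strand setting of the counting and the treatment of reads that map to several places. Members of families with near-identical copies, such as tubulins, profilins, histones and ubiquitins, can therefore share reads, and their values are uncertain to that extent. The sample sheets list the sequencing lanes. Controls 1, 2 and 3 and heat replicate 3 were run on the same 3 lanes, and heat replicates 1 and 2 on 2 other lanes.

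The table holds 39625 gene models, named by identifier. Names came from a RefSeq gene table of another maize assembly, release 5.0 of the B73 reference, which was used for names alone. It matched 19060 of the gene models, gave a name other than a locus or clone number to 2822 of them, and matched 521 models to more than 1 gene. Only 9.10% of the tested genes carried a name, so the gene lists are short and hold a small part of each pathway. The names are symbols without descriptions.

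Sequencing depth is not part of a TPM value, but it could be rebuilt. The ratio of a gene's values in different libraries is a ratio of whole numbers times a constant for the libraries. Whole reads and a whole gene length were recovered in this way for all 24654 gene models above 0 in any library, within a tolerance of 0.01 reads, and the read numbers implied by the values lay within 2.62e-09 of whole numbers. A common divisor was put back for 445 of them from their lengths; a divisor left in the counts of low genes cannot be excluded. On simulated values the method gave the right reads, up to a common divisor, for 100.00% of 18478 genes. The recovered totals were 28640667, 23247111 and 20978451 reads in controls 1, 2 and 3, and 19745003, 19533803 and 19086616 reads in heat replicates 1, 2 and 3.

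Genes with at least 1 TPM in at least 3 of the 6 libraries were tested, which left 8615. Differences between heat and control were tested on log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (linear model with an intensity trend in the variance, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. Every adjusted p for a gene comes from this limma fit unless another is named. The test was run on simulated reads drawn for the real genes at the real depths, with 200 changed genes in 8590 tested: it recovered 58.2% of genes changed 1.5-fold, 88.1% of those changed 2-fold and 93.9% of those changed 4-fold, and 8.57% of its calls were false. The spread of the simulated reads was the same for all genes, so these shares are approximate.

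Before the data were examined, 34 gene lists were fixed as patterns on names, together with the tests, the alternatives below that are not said to be later, and the rule for the genes named. A further 31 lists were written once the names and mean levels of the genes had been seen and before any test was run. Lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted within each of the 2 families of lists; camera with an estimated correlation and fry were run beside it. Under the rule, the genes named were the 12 largest rises and 12 largest falls among named genes past the threshold whose libraries did not overlap between groups and whose mean reached 5 TPM in the higher group; up to 2 rising and 2 falling members of each list, or its most abundant tested member where none passed; and the 10 most abundant named genes. Numbers of detected genes and shares of TPM were compared by exact permutation tests, two-sided, for which 3 libraries against 3 cannot give a p below 0.1. Libraries were checked for duplicates by a chi-square test of recovered reads within groups, where the smallest ratio of the statistic to its degrees of freedom was 6.68; no pair was within sampling noise.

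The alternatives were other pseudocounts (0.1 and 5), other filters on low values, rescaling by median ratios, TPM recomputed without the 100 most abundant genes, quantile normalization, robust variance estimates, array weights, the replicate number as a block, the lane as a covariate and the removal of each library. After the data had been seen, limma-voom on the recovered reads and thinning of all libraries to the smallest were added. A gene was tested in up to 19 alternatives. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 served for the read recovery and the plots.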

Results

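Transcript levels were measured by RNA sequencing in mature pollen of maize B73, in 3 control libraries and in 3 libraries from plants that had been heated for 48 h when their pollen was at the tetrad stage. Between 19086616 and 28640667 reads were recovered per library, and each control library was deeper than each heat library. Between 8168 and 8607 genes reached 1 TPM in a library. The most abundant named transcript was mgs1 (GRMZM2G317406), with 18389 ± 290.3 TPM in control and 18441 ± 568 TPM in heat (mean ± SD, n = 3 each), and it did not pass the test (adjusted p = 0.968). The pectin methylesterase gene pme1 (GRMZM2G125356) came next, and it fell from 8941 ± 159 to 7541 ± 340.4 TPM (log2 fold change -0.25, SE 0.05, adjusted p = 0.0048). The profilin gene prf2 (GRMZM2G109842) followed with 7183 ± 473 TPM in control and 7894 ± 373 TPM in heat (adjusted p = 0.136).

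The first question was how far the expression profile of mature pollen differed between the treatments. Correlations of log2(TPM + 1) across the tested genes were each higher within groups than between them. Pearson coefficients ran from 0.993 to 0.996 within groups and from 0.981 to 0.989 between groups, and Spearman coefficients from 0.974 to 0.983 and from 0.939 to 0.962. Over all genes above 0 the Spearman ranges overlapped, from 0.925 to 0.936 within and from 0.913 to 0.927 between groups. Genes are not independent replicates, so these coefficients are descriptions. The first principal component held 63.4% of the variance and separated the groups, with heat replicate 3, which shared its lanes with the controls, at 16.2, between heat replicate 1 at 10.9 and heat replicate 2 at 22.5.

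**Figure D1:**
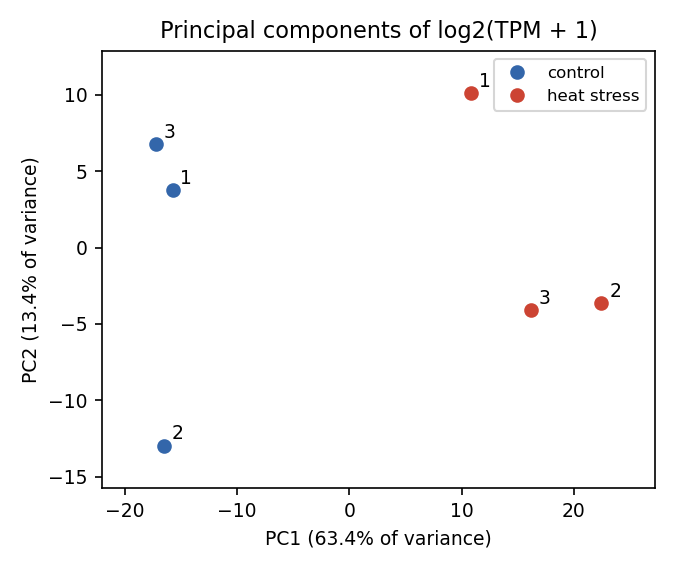
Scores of the 6 libraries on the first (63.4% of variance) and second (13.4%) principal components of log2(TPM + 1) over the 8615 tested genes. Points are libraries with their replicate numbers; controls lie at negative and heat libraries at positive scores on the first component.

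The main comparison asked which transcripts differed in mature pollen after heat at the tetrad stage. The MYB-related gene MYBR95 (GRMZM2G115070) rose most among named genes on the log2(TPM + 1) scale, from 4.18 ± 0.20 to 24.8 ± 3.65 TPM (log2 fold change 2.30, SE 0.12, adjusted p = 1.36e-07). TIFY20 (GRMZM2G173596), of the family that includes the JAZ repressors of jasmonate signalling, rose from 13.6 ± 0.34 to 68.0 ± 6.45 TPM (log2 fold change 2.23, SE 0.09, adjusted p = 1.99e-08). MYB-IF35 (GRMZM2G051256) rose by 1.84 on the log2 scale, as did bx6 (GRMZM6G617209), a dioxygenase gene of benzoxazinoid synthesis, and TIFY4 (GRMZM2G445634) rose by 1.74. On the same scale the largest falls among named genes were those of GLK44 (GRMZM2G124540), from 7.43 ± 0.27 to 2.36 ± 0.80 TPM (log2 fold change -1.35, SE 0.15, adjusted p = 7.36e-05), and Bk2L4 (GRMZM2G071970), from 5.04 ± 0.76 to 1.59 ± 0.79 TPM (log2 fold change -1.26, SE 0.19, adjusted p = 6.41e-04).

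Other large rises were those of PPR-814b (GRMZM2G416498; log2 fold change 1.29), the invertase gene ivr2 (GRMZM2G089836; 1.15), ARGOS6 (GRMZM2G162250; 1.14) and PINY (GRMZM2G050089; 1.06). The AP2/EREB gene EREB179 (GRMZM2G129674) fell from 70.9 ± 6.35 to 39.1 ± 1.77 TPM (log2 fold change -0.84). CIPK16 (GRMZM2G330049), a kinase gene of calcium signalling, fell by 0.99 and HMT-1 (GRMZM6G310687) by 0.89 on the log2 scale. The gene models without a name with the largest rises on that scale, past those of all named genes, were GRMZM5G805002, from 14.6 ± 3.54 to 96.0 ± 17.4 TPM, and GRMZM2G300044, from 15.1 ± 0.67 to 98.2 ± 10.4 TPM. The largest falls without a name, among genes with a mean of at least 5 TPM in the higher group, were those of GRMZM2G171468, from 19.0 ± 1.56 to 4.40 ± 1.96 TPM, and GRMZM2G099944, from 122.7 ± 1.28 to 37.3 ± 12.3 TPM. An absence of overlap between the 3 heat and the 3 control libraries was a condition for choosing these genes, so it adds no support. All 1739 genes past the threshold kept their direction under every alternative that tested them. For 1705 of them the libraries did not overlap between groups. The lane fit and the removal of a library could not reverse those, so their kept direction adds no support there. The 12 largest rises and 12 largest falls of named genes with a mean of at least 5 TPM in the higher group were among these 1705. Lower-lying genes such as hsp18c and pcna2 changed by more than some of these (log2 fold change 1.13 and -1.10). Of these 24, 17 passed the threshold with the lane as a covariate. CIPK16 did not (log2 fold change -0.99, SE 0.22, and with the lane -1.06, SE 0.32; adjusted p 3.56e-04 to 0.0687 over the alternatives, the highest with the lane), nor did HMT-1 (-0.89, SE 0.19, and with the lane -0.74, SE 0.28; adjusted p 5.12e-04 to 0.140). The fit with the lane takes the heat effect from heat replicate 3 against the controls, and its SE was a median of 1.46 times larger over all tested genes. The 1117 calls that it ended had a median of 0.918 times their log2 fold change.

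**Figure D2:**
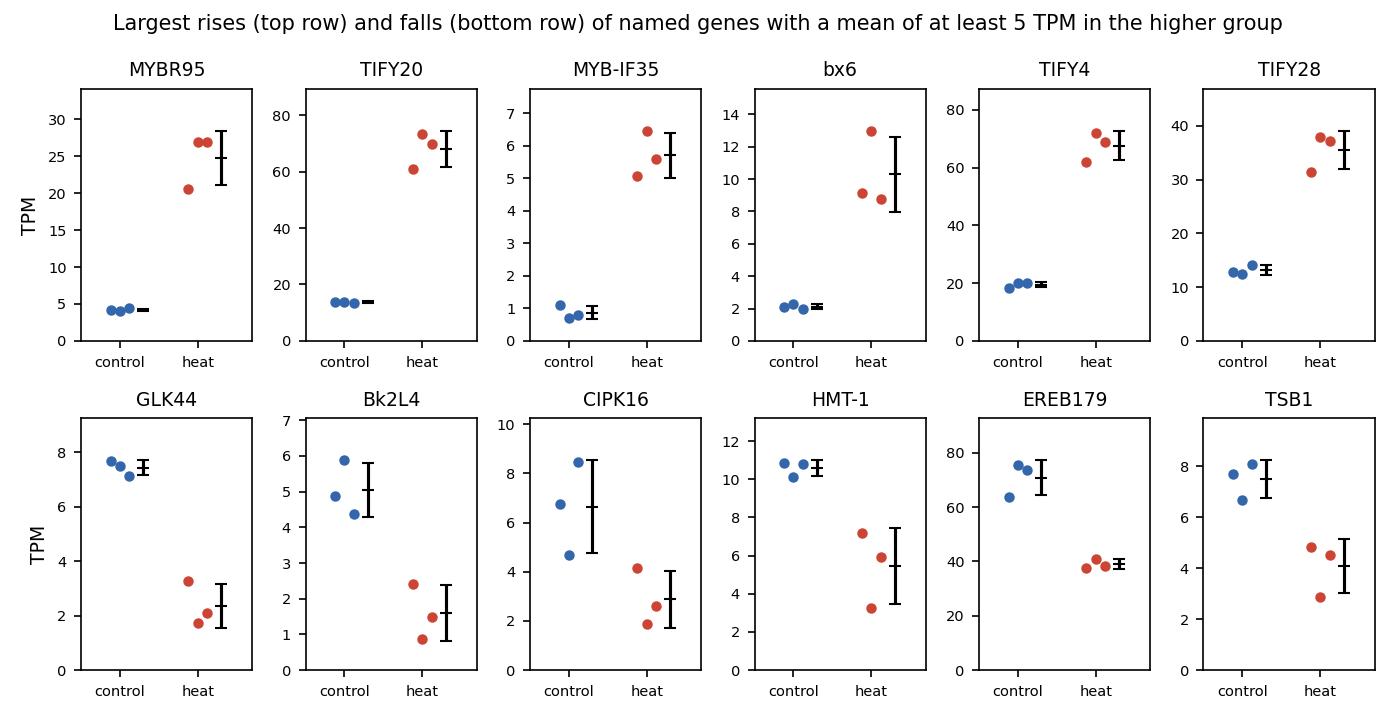
TPM of the 6 largest rises (top row) and the 6 largest falls (bottom row) of named genes with a mean of at least 5 TPM in the higher group, by log2(TPM + 1). Points are single libraries, 3 per group, and bars give the mean ± SD. Groups that do not overlap were a condition for choosing these genes. MYBR95 had 4.18 and 24.8 TPM on average in control and heat.

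Across all genes, limma placed 1739 of 8615 past the threshold (20.2%), 1123 higher and 616 lower after heat. With single libraries removed, the lower genes ran from 374 (without control replicate 1) to 682 (without heat replicate 1). The higher genes ran from 813 (without heat replicate 2) to 1138 (without heat replicate 1). Of the 1739, 1042 (59.9%) were under 1.5-fold, a share that ran from 18.8% with the lane as a covariate to 84.0% with a pseudocount of 5. A change of 2-fold was reached by 199, 128 of them higher and 71 lower, against 387 with a pseudocount of 0.1, 60 with a pseudocount of 5, 330 without the 100 most abundant genes and 400 with limma-voom. In that order the higher and lower numbered 209 and 178, 52 and 8, 167 and 163, and 211 and 189. The lower ones numbered 47 without heat replicate 2 and 112 without heat replicate 1. Control and heat libraries did not overlap for 3146 genes (36.5%), where chance gives 10%. Median-ratio scaling gave 1043 higher and 730 lower, TPM without the 100 most abundant genes 894 and 874, and quantile normalization 871 and 953. The excess of higher over lower genes was thus nearly gone without the 100 most abundant genes and reversed after quantile normalization. With the lane as a covariate, 435 genes were higher and 219 lower. Within the lanes shared by both groups, heat replicate 3 against the 3 controls gave 994 genes. There the spread came from the controls, and the lone heat library was assumed to vary like them. Heat replicates 1 and 2, on other lanes, gave 692 and 1477 genes in the same way. The other lanes held heat libraries alone.

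**Figure D3:**
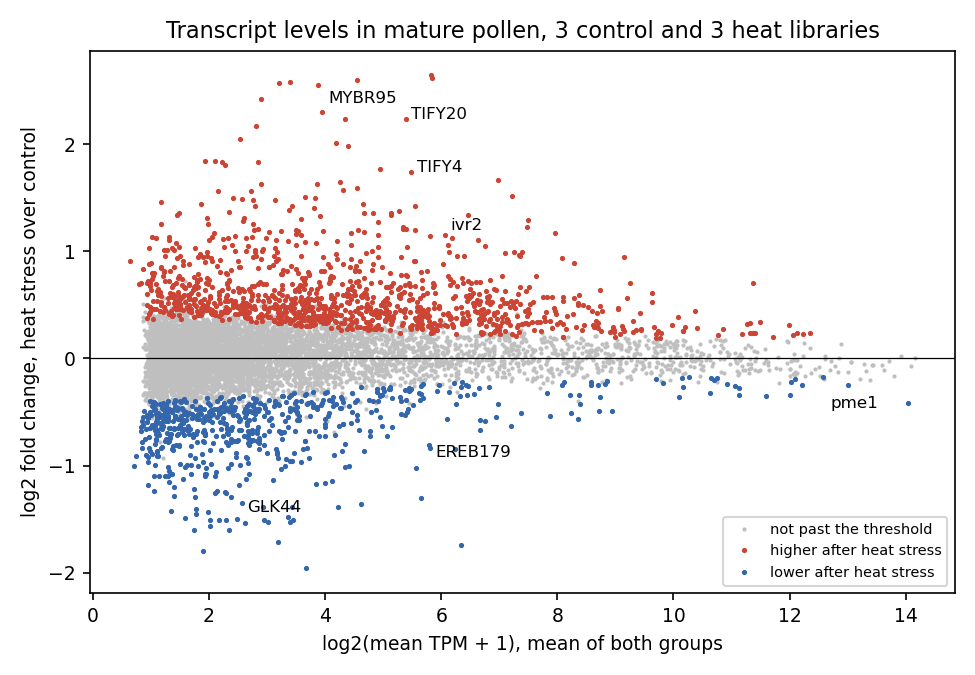
Log2 fold change of heat over control (vertical axis) against the mean level as log2(mean TPM + 1) (horizontal axis) for the 8615 tested genes, each a point. The 1123 higher and 616 lower genes are coloured; MYBR95 at 2.30 and GLK44 at -1.35 are among the named genes with the largest changes.

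The next question was whether genes of the heat response still differed in mature pollen. The small heat shock protein gene hsp18c (GRMZM2G034157) rose from 0.264 ± 0.103 to 1.78 ± 0.40 TPM (log2 fold change 1.13, SE 0.14, adjusted p = 1.26e-04), while hsp18a (GRMZM2G404249) fell from 2.02 ± 0.30 to 0.787 ± 0.172 TPM (log2 fold change -0.75, SE 0.13, adjusted p = 0.0018). Of 3 tested heat shock factor gene models 1 rose, 1 fell and 1 was not called. Hsf01 (GRMZM2G165998, matched to more than 1 gene) was higher by 0.53 on the log2 scale and Hsf05 (GRMZM2G132971) lower (log2 fold change -0.44). A further model named Hsf05 (GRMZM2G133023), picked after its values were seen, was not called. It was more abundant, at 4.47 TPM in control and 3.94 TPM in heat. Below, Hsf05 stands for GRMZM2G132971. The disaggregase gene hsp101 (GRMZM2G360681) was far more abundant, at 112.0 ± 6.74 TPM in control and 135.8 ± 4.45 TPM in heat (log2 fold change 0.28, SE 0.07, adjusted p = 0.0156). The most abundant of the 2 tested HSP70 genes, hsp70-4 (GRMZM2G340251), had 2.08 and 2.18 TPM (adjusted p = 0.810), and limma called neither of them; at an unadjusted p under 0.05 the count was also 0, as with limma-voom. The filter left out 3 of 5 small heat shock protein genes, 3 of 5 HSP70 and BiP genes, all 3 HSP90 genes and 8 of 11 heat shock factor genes. With no filter, limma called 2 of these, named after their values were seen: hsp18f (GRMZM2G083810), with 0.182 ± 0.140 TPM in control and 0.856 ± 0.222 TPM in heat (log2 fold change 0.65, SE 0.14, adjusted p = 0.0292), and Hsp70 (GRMZM2G310431), with 0.167 ± 0.0815 and 0.738 ± 0.0617 TPM (0.58, SE 0.11, 0.0163). These lists had too few tested members for camera, and the same numbers passed when adjusted over the list alone. A list of all heat shock names, added later, had 11 tested genes, of which 3 rose, 2 fell and 6 were not called, and its camera p was 0.589 (0.649 with an estimated correlation). The call of hsp101 was lost without control replicate 2 (adjusted p = 0.0504), control replicate 3 (0.0555) or heat replicate 2 (0.0513), and its adjusted p ran from 0.0068 to 0.307 over the alternatives. That of Hsf05 was lost without control replicate 1 (0.0935), 2 (0.0553) or 3 (0.0567) and without heat replicate 1 (0.0520) or 2 (0.0889), with a range from 0.0073 to 0.334. Among these 5 genes hsp18c alone kept its call with the lane as a covariate. The log2 fold change without and with the lane was -0.75 and -0.67 for hsp18a (adjusted p from 9.01e-04 to 0.0611 over the alternatives), 0.53 and 0.52 for Hsf01 (0.0026 to 0.134), -0.44 and -0.31 for Hsf05 and 0.28 and 0.23 for hsp101. The SE of these 4 genes lay between 0.07 and 0.13 without and between 0.11 and 0.20 with the lane. Under quantile normalization hsp101 had a log2 fold change of 0.09 and gave its highest adjusted p.

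Carbohydrate metabolism was examined because starch and sugars feed the growing pollen tube. Of 6 tested genes of sucrose metabolism and sugar transport 2 rose and 4 were not called: ivr2 from 40.3 to 91.1 TPM on average (log2 fold change 1.15, SE 0.12, adjusted p = 4.71e-05), and IVR1 (GRMZM2G394450) from 35.0 ± 4.60 to 43.5 ± 2.10 TPM (adjusted p = 0.0389). A list of sugar and polyol transporters, added later, had 8 tested genes, of which 3 rose, 2 fell and 3 were not called (camera adjusted p = 0.6745). Only the calls of ERD6 (GRMZM2G097768, log2 fold change 0.53) and glct1 (GRMZM2G153704, -0.62, matched to more than 1 gene) held under every alternative. Of 12 tested genes of glycolysis and fermentation 4 rose and 8 were not called, and 7 rose when adjusted over the list alone. The enolase gene eno1 (GRMZM2G064302) rose from 71.9 ± 4.03 to 112.0 ± 23.7 TPM (adjusted p = 0.0038), and the aldolase gene ald1 (GRMZM2G057823) from 354.6 ± 14.4 to 496.6 ± 13.6 TPM (adjusted p = 1.36e-04). The others, named after their values were seen, were gpi (GRMZM6G477257; log2 fold change 0.34) and PDC (GRMZM2G087186; 0.30). Limma called 0 of the 7 tested genes of starch synthesis, as did limma-voom, and 0 had an unadjusted p under 0.05; the most abundant of them, the branching enzyme gene ae1 (GRMZM2G032628), had 17.0 ± 0.77 TPM in control and 18.0 ± 0.19 TPM in heat (adjusted p = 0.569). A wider list of starch enzymes, added later, had 13 tested genes, of which AGP2 (GRMZM2G027955) fell, from 16.5 ± 2.44 to 11.9 ± 1.75 TPM (adjusted p = 0.0293), and 12 were not called; adjusted over the list alone 0 fell and 0 rose.

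Neither the glycolysis list (camera p = 0.0053, adjusted p = 0.0856; p = 0.302 with an estimated correlation) nor the starch lists (adjusted p = 0.499 and 0.251) nor the sucrose list (adjusted p = 0.499) passed camera. The adjusted p of the glycolysis list was 0.0332 without heat replicate 1 and 0.0368 without heat replicate 3, and ran from 0.0074 to 0.792 over the alternatives. Under every alternative ivr2 and ald1 kept their calls. By contrast eno1 lost its own with the lane as a covariate, where its log2 fold change stayed at 0.61 and its SE went from 0.12 to 0.18 (adjusted p from 1.12e-04 to 0.0675 over the alternatives). IVR1 lost its call without control replicate 1 (0.152) or 2 (0.119) and without heat replicate 1 (0.0905), 2 (0.0769) or 3 (0.0671), with a range from 0.0125 to 0.346. Its log2 fold change was 0.31 (SE 0.10), 0.25 (SE 0.14) with the lane and 0.17 (SE 0.09) after quantile normalization (0.223). AGP2 lost its call without control replicate 1 or 3 and without heat replicate 2 or 3 (0.0823 to 0.140) and with the lane (log2 fold change -0.43, SE 0.13, and with the lane -0.51, SE 0.19; adjusted p = 0.133), with a lowest adjusted p of 0.0058 over the alternatives. The call of gpi was lost without control replicate 1 (0.0796) or 2 (0.0561) and without heat replicate 2 (0.0715). It was also lost with the lane (log2 fold change 0.34, SE 0.09, to 0.16, SE 0.11; adjusted p = 0.457, the highest over the alternatives) and after quantile normalization (0.15, SE 0.08; adjusted p = 0.223). That of PDC was lost without any single library (0.0655 to 0.131), with the lane (0.30, SE 0.10, to 0.22, SE 0.15; adjusted p = 0.435, the highest) and after quantile normalization (0.22, SE 0.09; 0.0905).

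**Figure D4:**
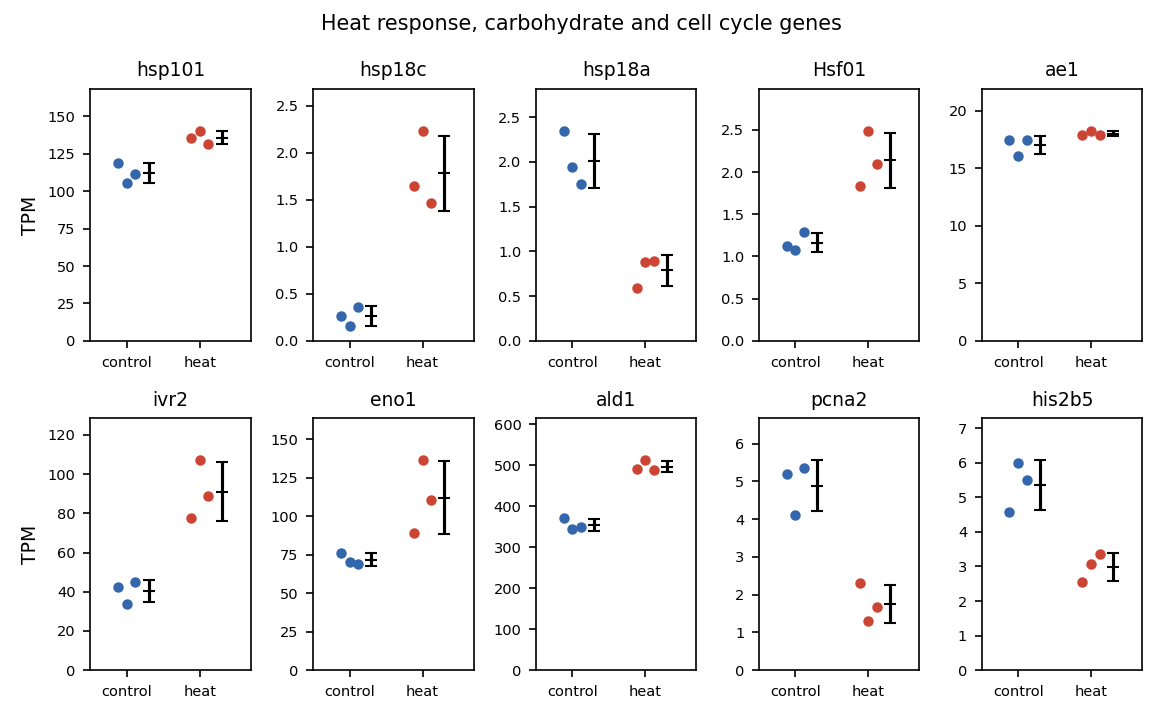
TPM of genes of the heat response (hsp101, hsp18c, hsp18a, Hsf01), of carbohydrate metabolism (ae1, ivr2, eno1, ald1) and of replication and chromatin (pcna2, his2b5). Points are single libraries, 3 per group, and bars give the mean ± SD; ivr2 had 40.3 TPM in control and 91.1 TPM in heat on average, and ae1 17.0 and 18.0 TPM.

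Genes for the growth machinery of the pollen tube were examined next. Of 24 tested actin, tubulin and associated genes 5 rose and 19 were not called, and 7 rose when adjusted over the list alone. The tubulin gene TUBB2 (GRMZM2G334899) rose from 29.7 ± 2.05 to 45.6 ± 6.06 TPM (log2 fold change 0.60, adjusted p = 0.0013), and the profilin gene prf3 (GRMZM5G876285; matched to more than 1 gene) from 2178 ± 60.5 to 2729 ± 185 TPM (log2 fold change 0.32, adjusted p = 0.0023). The others were tub5 (GRMZM2G133802; 0.37), prf1 (GRMZM2G074361; 0.33) and, named after its values were seen, an actin gene (GRMZM2G126190, actin; 0.37). Among 6 tested Rop and calcium signalling genes, rop2 (GRMZM5G846811) rose from 176.0 ± 7.85 to 211.5 ± 7.90 TPM and cdpk1 (GRMZM2G115518) fell from 413.3 ± 4.08 to 348.0 ± 12.8 TPM. Among 9 tested genes of ion transport and aquaporins 2 rose, the aquaporin gene SIP2-1 (GRMZM2G175038) by 0.75 and TIP1-2 (GRMZM2G168439) by 0.35 on the log2 scale. The same numbers of genes passed in the signalling and transport lists when adjusted over the list alone. Neither the cytoskeleton list (p = 0.0175, adjusted p = 0.140; p = 0.43 with an estimated correlation) nor the signalling and transport lists (adjusted p = 0.757 and 0.499) passed camera. The adjusted p of the cytoskeleton list was 0.0339 without heat replicate 3 and ran from 0.0153 to 0.792 over the alternatives. TUBB2 and SIP2-1 kept their calls under every alternative, whereas with the lane as a covariate the other 7 genes (adjusted p from 0.0545 to 0.230) lost theirs. Their log2 fold change without and with the lane was 0.32 and 0.31 for prf3, 0.37 and 0.30 for tub5, 0.33 and 0.25 for prf1, 0.37 and 0.32 for actin, 0.26 and 0.23 for rop2, -0.25 and -0.28 for cdpk1 and 0.35 and 0.37 for TIP1-2. The SE of these genes lay between 0.06 and 0.09 without and between 0.09 and 0.13 with the lane. Quantile normalization also ended the calls of rop2 (log2 fold change 0.11, SE 0.06, adjusted p = 0.206), actin (0.17, SE 0.09, 0.197), tub5 (0.18, SE 0.06, 0.0676) and TIP1-2 (0.18, SE 0.07, 0.0848). Calls were also lost without control replicate 3 for prf1 (0.0563) and actin (0.0520), and without heat replicate 2 for rop2 (0.0516). A list of potassium, sodium and proton transporters, added later, had 12 tested genes, of which 5 rose, 2 fell and 5 were not called (camera adjusted p = 0.7216). None of the calls in that list held under every alternative. A wider list of calcium signalling genes, added later, had 22 tested genes, of which 3 rose, 4 fell and 15 were not called (camera adjusted p = 0.801). There only the call of CDPK (GRMZM2G047486, log2 fold change 1.03) held under every alternative. Of 9 aquaporin genes on another added list 3 rose and 6 were not called (camera adjusted p = 0.426). Of these, TIP2-3 (GRMZM2G125023, 0.53) and SIP2-1 held under every alternative.

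Stress, folding and regulatory lists held further single genes that changed. The protein disulfide isomerase gene pdi7 (GRMZM2G159369) rose from 25.7 ± 0.58 to 37.9 ± 2.39 TPM (adjusted p = 6.22e-04) and pdi4 (GRMZM2G034143; matched to more than 1 gene) by 0.36 on the log2 scale, the 2 rising genes among 7 tested for folding in the endoplasmic reticulum. The translation factor gene eIF-4A (GRMZM2G116034) rose from 15.5 ± 0.98 to 28.4 ± 4.05 TPM (adjusted p = 1.84e-04), the only called gene among 5 translation factors. Of 19 tested genes on the fixed transcription factor list 5 rose and 14 were not called. The 5 were MYBR95, MYB-IF35, MYBR22 (GRMZM2G468479, log2 fold change 1.08), MADS76 (GRMZM2G070034, 0.79) and, named after its values were seen, MYBR26 (GRMZM2G112764, 0.59). Adjusted over the list alone 5 rose and 2 fell, and the median of this list (-1.69e-04) was negative while its mean (0.31) and the camera direction were positive. The name patterns of this list missed other factor genes, such as EREB179, which fell. In lists added later, 2 rose and 1 fell of 5 tested AP2/EREB genes, and 1 rose and 2 fell of 10 MADS genes. Of 7 bHLH genes 2 rose, of 5 NAC genes 1 fell, and of 8 MYB genes 3 rose, all named above. Of 3 bZIP and 2 WRKY genes 0 were called. Of 6 tested lipid genes 2 fell, as when adjusted over the list alone: the desaturase genes fad7 (GRMZM2G128971; log2 fold change -0.65) and fad8 (GRMZM2G074401; -0.42). The lane as a covariate ended the calls of pdi4 (log2 fold change 0.36, SE 0.09, to 0.26, SE 0.12; adjusted p from 0.0069 to 0.254 over the alternatives), fad7 (-0.65, SE 0.14, to -0.66, SE 0.20; 0.0022 to 0.0749) and fad8 (-0.42, SE 0.11, to -0.46, SE 0.16; 0.0046 to 0.113). The call of pdi4 was also lost after quantile normalization (0.21, SE 0.07; 0.0675). The call of fad8 was also lost without control replicate 1 (0.0720) or 3 (0.0588) and without heat replicate 2 (0.0560) or 3 (0.0581).

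Of the 34 fixed lists, 16 had enough tested members for camera and 0 passed after adjustment; 2 had an unadjusted p under 0.05, 0 did with an estimated correlation, and fry gave 0 after adjustment. Of the 31 lists added later 25 were tested and 1 passed, that of the TIFY genes (p = 0.0846, adjusted p = 0.835 with an estimated correlation); 5 had an unadjusted p under 0.05, and 0 passed when both families were adjusted together. With an estimated correlation 1 added list, that of the histones, had an unadjusted p under 0.05 and 0 passed after adjustment.

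Markers of other cells were examined because pollen samples can carry anther tissue. The photosynthesis genes, 21 in number, summed to 4.15 TPM in control and 4.35 TPM in heat. Of this sum psat1 (GRMZM2G300801) held 1.88 TPM in control and 2.53 TPM in heat, so the rest of the list did not rise in sum. As psat1 was listed by its symbol alone, its role in photosynthesis was not checked. The 4 tapetum and anther wall genes summed to 3.10 and 4.21 TPM, and 1 of their 2 tested members, ms32 (GRMZM2G163233; matched to more than 1 gene), rose from 1.62 ± 0.22 to 3.17 ± 0.11 TPM (adjusted p = 0.0021; 1.98e-04 to 0.0602 over the alternatives, the highest with the lane as a covariate, where the log2 fold change went from 0.67, SE 0.12, to 0.63, SE 0.18). The 46 genes of endosperm storage and transfer cells, a list added later, summed to 0.217 and 0.260 TPM. The sperm cell gene hap2 (GRMZM2G412911) had 6.86 ± 0.94 TPM in control and 7.42 ± 0.55 TPM in heat and did not pass the test (adjusted p = 0.596).

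The make-up of the libraries was compared last. The 100 most abundant genes held 55.6 ± 0.916% of all TPM in control and 53.5 ± 0.484% in heat (SD, n = 3 each), a difference for which the exact permutation test gave p = 0.1, the smallest it can give here. The 10 most abundant genes held 14.9 ± 0.594% and 13.8 ± 0.208% (exact permutation p = 0.1, n = 3 each). The number of genes at 1 TPM or more was 8453 ± 247 in control and 8384 ± 60.7 in heat (exact permutation p = 0.7, n = 3 each), a difference smaller than the spread between control libraries. Heat minus control was -69 genes at that limit, -243 at 0.1 TPM (exact permutation p = 0.4) and 52.3 at 5 TPM (exact permutation p = 0.7).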

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

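The tests on recovered reads and on thinned libraries were chosen after the data had been seen; the others were planned. The number of changed genes (1739) stayed within 1.5 times of that value in each alternative except the lane covariate, which gave 654, of which 622 were among the 1739; this fit compares heat replicate 3 with the controls, and it called 1 gene for the lane itself. Without each library in turn it ran from 1218 to 1820. The replicate block, for numbers that need not mark shared plants, gave 1785 genes; deviations of same-numbered libraries correlated at 0.12, 0.13 and -0.05, so the numbers were not taken to pair the libraries. The number of genes changed at least 2-fold (199) was 387 with a pseudocount of 0.1, 60 with a pseudocount of 5, 131 with a filter of 5 TPM, 330 without the 100 most abundant genes and 400 with limma-voom on recovered reads; it ran from 162 to 259 without each library. A larger pseudocount shrinks the fold change of low genes and the filter removes them by construction; the cause of the other shifts was not tested. The share of changed genes that were higher (64.6%) was 50.6% without the 100 most abundant genes and 47.8% after quantile normalization, and ran from 56.8% to 69.3% without each library. None of the fixed gene lists passed, but 2 did with no filter on low values, and 0 to 2 did without each library. Of the lists added later 1 passed; 2 did with a pseudocount of 0.1 and with no filter, 0 with a filter of 5 TPM, with median-ratio scaling, with quantile normalization and with camera at an estimated correlation, 7 with fry, which does not compare a list with other genes, and 0 to 2 without each library. The difference in detected genes, -69 in heat at 1 TPM, was 52.3 at 5 TPM, both with an exact permutation p of 0.7, and -243 at 0.1 TPM (p = 0.4). The mean Spearman correlation between groups was 0.951 over tested genes and 0.919 over all genes above 0, against 0.978 and 0.929 within groups; the cause was not tested. Of 107 named genes 90 were called in the main fit. Of the 107, 47 kept their side of the threshold in every alternative, which includes genes that never passed, such as mgs1, ae1 and hap2. None of the 90 calls changed sign, which the lane fit and the removal of a library could not bring about where groups do not overlap. The lane covariate ended 57 of these calls and the fit with no filter 26. Depth limits low genes most, and all control libraries were deeper; thinning to the smallest library ended 6 of these calls.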

Other observations

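The tests on markers of other tissues, the lane test of the TIFY genes, the test of jasmonate synthesis and the count of splits for the added lists were chosen after their results had been seen. TPM without the 100 most abundant genes was planned as an alternative, but its use as a test of the excess of rises was chosen after its result had been seen. Thinning was added after the data had been seen, though before its own result, and the others were set out before. Among lists written after the gene names had been seen, the TIFY/ZIM list was the 1 that passed (adjusted p = 0.0414), and it did not pass with an estimated correlation (p = 0.0846, adjusted p = 0.835). Of 13 tested members 5 rose and 8 were not called, as when adjusted over the list alone: TIFY20, TIFY4, TIFY28 (13.2 ± 0.88 to 35.5 ± 3.53 TPM), TIFY24 (16.5 ± 1.06 to 33.8 ± 1.90 TPM) and TIFY30, named after its values were seen (6.62 to 8.83 TPM, limma adjusted p = 0.0423). TIFY30 passed in 9 of 19 alternatives and lost its call without control replicate 1 (0.136), 2 (0.0528) or 3 (0.114) and without heat replicate 2 (0.160) or 3 (0.0625); the other 4 kept theirs in all 19. TIFY29, the most abundant at 524.0 TPM in control and 521.5 TPM in heat, did not pass (adjusted p = 0.946) and was also picked after its values were seen. Camera gave p = 0.0017 for this list, with an adjusted p of 0.0414 within the 25 added lists tested, 0.068 over both families of lists, and p = 0.0846 (adjusted p = 0.835) with an estimated correlation. The adjusted p within the added lists ran from 2.20e-04 to 0.835 over the alternatives and was 0.0950 without heat replicate 3. Of 5 tested genes of jasmonate and oxylipin synthesis 2 rose, as when adjusted over the list alone: the cyclase gene aoc2 from 3.41 ± 0.49 to 5.23 ± 0.48 TPM and the reductase gene opr7 from 18.9 ± 2.03 to 26.5 ± 0.77 TPM. Without control replicate 1 (adjusted p = 0.0580) or heat replicate 2 (0.0558) aoc2 lost its call, and both lost it with the lane as a covariate (0.180 and 0.0695, the highest over their alternatives; the lowest were 0.0097 and 0.0014). There the log2 fold change went from 0.50 (SE 0.13) to 0.46 (SE 0.19) for aoc2 and from 0.47 (SE 0.10) to 0.48 (SE 0.14) for opr7; that of TIFY30 went from 0.36 (SE 0.11) to 0.27 (SE 0.17), with its highest adjusted p, 0.393.

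Genes of DNA replication and chromatin included falls. Of 11 tested genes of the cell cycle and DNA replication 3 fell and 8 were not called; adjusted over the list alone 3 fell and 1 rose. The replication clamp gene pcna2 fell from 4.88 ± 0.68 to 1.76 ± 0.51 TPM (limma adjusted p = 3.11e-04) and krp11 from 1.85 ± 0.16 to 0.524 ± 0.238 TPM. PCNA (GRMZM2G030523), named after its values were seen, fell from 2.42 to 1.32 TPM. All 3 passed in all 18 alternatives that tested them. As krp11 was listed by its symbol alone, its role in the cell cycle was not checked. Of 7 tested histone genes 2 fell, his2b5 from 5.35 ± 0.72 to 3.00 ± 0.41 TPM and H4C13 (GRMZM2G181153) from 8.92 ± 0.94 to 5.75 ± 0.45 TPM, and 1 rose, the centromeric histone gene cenH3 (matched to more than 1 gene), from 0.778 to 1.47 TPM. Adjusted over the list alone 5 histone genes fell and 1 rose. The histone list had a camera p of 0.0042 (adjusted p = 0.0531; p = 0.0422 with an estimated correlation). Its adjusted p was 0.0383 without control replicate 1 and 0.0349 without control replicate 3, and ran from 0.0155 to 0.835 over the alternatives. The list of histones and chromatin fixed beforehand also had 7 tested genes, of which 1 rose, 1 fell and 5 were not called. Adjusted over that list alone 2 rose and 2 fell. Its camera p was 0.549 (adjusted p = 0.732), and 0.576 with an estimated correlation. The cell cycle list had an adjusted p of 0.675; its median (0.10) was positive while its mean (-0.12) and the camera direction were negative. The lane as a covariate ended the calls of his2b5 (log2 fold change -0.67, SE 0.13, to -0.53, SE 0.19; adjusted p from 0.0018 to 0.120 over the alternatives), H4C13 (-0.55, SE 0.11, to -0.51, SE 0.17; 0.0035 to 0.0990) and cenH3 (0.47, SE 0.14, to 0.42, SE 0.20; 0.0154 to 0.254). The call of cenH3 was also lost without control replicate 1 (0.0993), 2 (0.0684) or 3 (0.0756) and without heat replicate 2 (0.126) or 3 (0.0643).

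Other splits of the 6 libraries into 3 and 3 number 10 with the real one, too few for a share under 0.05. Each of the others mixes heat and control libraries in both groups. A difference between the treatments, whatever its cause, then widens the spread within groups and lowers the gene counts, so low counts there cannot tell causes apart. The real split gave 1739 changed genes and the highest of the others 0; it was 1 of 10 splits with a count that large. For genes changed at least 2-fold the real split gave 199 and the highest other 0, again 1 of 10. For the fixed lists the real split gave 0 lists and the highest other 1; all 10 of 10 reach a real count of 0, whatever they give. The splits that gave 1 were those that set heat replicates 1 and 2 apart from heat replicate 3, as the lanes do. For the added lists the real split gave 1 list and the highest other 2, and 3 of 10 splits gave at least 1: the real one, control 1 with heat replicates 1 and 2, which also keeps the other lanes together, and control 1 with heat replicates 2 and 3. With the lane as a covariate 0 fixed lists and 1 added list, that of the TIFY genes, passed; with an estimated correlation the TIFY list did not (p = 0.0846, adjusted p = 0.835).

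More genes rose than fell, though after quantile normalization more fell than rose (871 higher and 953 lower, 47.8% higher). The depth of the control libraries is argued against as the cause, since 65.0% of calls were higher with all libraries thinned to the smallest. Gene length is also argued against as the whole cause, since more genes rose than fell in each of 4 length groups of similar size. From the shortest to the longest, the higher and lower genes numbered 304 and 160, 265 and 159, 287 and 139, and 267 and 158. The median log2 fold change of the longest minus that of the shortest was -0.0162. Beside a median of 0.0393 over all tested genes, that difference cannot exclude a small part for length. RNA from green tissue or endosperm is argued against too. Neither list of its marker genes gained more than 0.0045% (with 2 SE added) of the summed TPM rise of the higher genes. The more abundant list was led by psat1 at 2.53 TPM in heat, a gene listed by its symbol alone. RNA from the anther wall stays open: its markers gained 0.0050% in the same way, but they are 4 genes, of which ms32 rose to 3.17 TPM. The lower share of TPM in the 100 most abundant genes stays open and may account for the excess, because the share of higher calls was 50.6% without them. After median-ratio scaling 58.8% of calls were still higher (1043 higher and 730 lower). Values relative to a total cannot show whether the amount of RNA per grain changed.

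The difference between heat and control pollen might in part reflect the lanes. Genes called between heat replicates 1 and 2 and 2 of the controls went the same way in heat replicate 3 against the remaining control in 97.2% of cases, although heat replicate 3 shared its lanes with the controls, which argues against the lane as the whole cause. With the lane as a covariate 654 genes passed the threshold. A contribution of the lane to single genes stays open, since heat replicate 3 is the only heat library on those lanes.

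Of the 13 tested TIFY genes 5 rose and 8, the abundant TIFY29 among them, were not called; the list passed within the added lists alone (adjusted p = 0.0414; 0.068 over both families; p = 0.0846 and adjusted p = 0.835 with an estimated correlation), so a link to jasmonate signalling is a hypothesis. Lane is argued against as the cause of the rises of TIFY20, TIFY4, TIFY28 and TIFY24. Their log2 fold changes were 2.23, 1.74, 1.36 and 0.99 in the main fit and 2.27, 1.77, 1.43 and 0.96 with the lane as a covariate. These 4 of the 5 rising genes kept their calls there. For TIFY30 the lane stays open, with a log2 fold change of 0.41 without heat replicate 3 and 0.27 with the lane. Over all 13 tested members the median difference from control in heat replicate 3 was 0.989 times that in heat replicates 1 and 2. As 8 of the 13 were not called, this median does not measure the rises themselves. RNA from green tissue or endosperm is argued against by its markers, of which neither list gained more than 1.02% (with 2 SE added) of the summed TPM rise of these 5 genes; RNA from the anther wall stays open, since its 4 markers, of which ms32 rose, are too few (1.14%). A jasmonate response may be a candidate explanation, but the list of jasmonate and oxylipin synthesis genes gave a camera p of 0.0586, which decides nothing, and reads shared between family members were not tested.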
